A study of Homo sapiens with 6 samples.

How the data were processed

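Gene expression was measured by RNA sequencing in 6 HepG2 libraries, 3 from cells given 50 µM EA and 3 from cells given DMSO, after 24 h. Per the labels' protocols, total RNA was extracted with TRIzol, samples with an integrity number above 7 were used, 1 µg went into NEBNext Ultra libraries, and paired reads of 150 bp were sequenced on a HiSeq instrument. Per the submitters' processing notes, bcl2fastq 2.17.1.14, cutadapt 1.9.1, HISAT, HTSeq 0.6.1 and the hg19 build were used. The HISAT version, the annotation release, the strand setting of the counting and any filter are not given in the sources used here, so reads of antisense and overlapping genes cannot be told apart.

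The authors deposited a table of raw counts, whole numbers of reads per gene that are not normalised, for 52408 genes named by symbol, Ensembl identifier and gene class. Each of the 6 count columns was matched to its sample by name. All 37 genes named MT- were listed at 0, and how these came to be 0 is not given in the sources used here. Libraries held 22987425 to 25973621 reads in DMSO and 15738089 to 19202292 in EA, so a count of 0 in 1 library allows up to 0.116 to 0.191 CPM (3 reads). Such floors and the intervals of count ratios cover counting error only, since reads without molecular identifiers are not independent molecules.

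From these counts, genes were filtered with filterByExpr, which left 15648, libraries were scaled by TMM, and EA was compared with DMSO by edgeR's quasi-likelihood F test (edgeR 4.0.16, R 4.3.3, robust estimation) with Benjamini-Hochberg adjustment. The common biological coefficient of variation was 7.96%. Levels are CPM with TMM-scaled library sizes, and the SE of a log2 fold change was taken as its size over the square root of F. Gene lists with at least 3 tested members were tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset inter-gene correlation of 0.01, with an estimated correlation and fry beside it. The 30 lists hold 467 distinct genes, of which 4 entries were matched through older symbols and 3 (UHRF1, ACACA and PECAM1) were not matched and are not analysed here. Among matched members, 58 genes were below the filter, including CYP51A1, EBP, INSIG1 and ME1. These had few or no reads in all libraries, which may come from the counting or annotation and need not mean low expression.

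Genes were named by a rule, planned ahead of the values. Among called genes with a symbol, a mean CPM of at least 1 and all EA libraries on one side of all DMSO libraries, the rule took the 8 largest increases and 8 largest decreases, the 4 higher and 4 lower genes with the smallest p, and up to 4 called members with the smallest p in each list. Some genes that this rule takes are not reported here. That a clone-based name is not a symbol was decided after values had been seen. Against a group with 0 reads a fold is a lower bound computed from 3 reads over the group; with 1 to 3 reads the ratio is given with its 95% exact counting interval. Outside this rule, and after their values were seen, BAX, APOA1, ETV4, ETV5, CSF1R, CD14, the members that went against their lists, the family members and the silent genes were named. Transcript length, GC content and gene neighbours came from GENCODE 29 on GRCh38, another build than the submitters' hg19, so no coordinates are given; 99.9% of tested genes had a length and GC value.

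The test was checked on simulated counts for the EA and DMSO comparison with 15212 genes, some given known changes. It recovered 30, 40, 48 and 50 of 50 genes changed 1.5-fold, 2-fold, 4-fold and 8-fold (60%, 80%, 96% and 100%). The 19 false calls were a larger share of the calls in this simulation than the adjusted p threshold of 0.05 aims at. All other simulated genes were equal between the groups, whereas most real genes were called, so these rates may not carry over to the data. The alternatives chosen ahead of the values were DESeq2 1.42.0, limma-voom, RLE, upper-quartile and library-size scaling, no filter, a stricter filter of 1 CPM in 3 libraries, a minimum fold of 1.2, an adjusted p of 0.01, correction for GC content and length, a block for the replicate number, and each library left out in turn. Added after the data were seen were thinning to equal depth, removal of the 20 genes with the most reads, and the list tests after GC and length correction. A further test, of whether GC content and length account for the fall of respiratory chain genes, was set before its result and is given only as a value, because at most 3 patterns are weighed. For the chromosome test, set once the overall results were known, the first rule labelled the largest difference of 0.28 as speaking against another line. The rule was changed after that value was seen so that each difference plus 2 SEs had to stay small, which gave the label that the explanation cannot be told apart. Gene families by symbol were defined after values had been seen and partly from genes that had stood out, so no p is given for them. Figures were drawn with matplotlib 3.10.9.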

Results

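RNA was sequenced from HepG2 cells, a human liver cancer line that keeps many traits of hepatocytes. The cells had been kept for 24 h with 50 µM ellagic acid (EA), a plant polyphenol found in berries and nuts, or with the same volume of its solvent DMSO. Each group had 3 libraries, and the labels do not say that these came from separate cultures, so p-values measure only the spread between these samples, which may be technical. Reads assigned to genes numbered 25973621, 22987425 and 25500940 in the DMSO libraries and 15738089, 18891478 and 19202292 in the EA libraries. The comparison of EA with DMSO asks which genes and signalling pathways the compound changes in hepatocellular carcinoma cells.

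Most genes differed in expression between HepG2 cells given EA and those given DMSO. In a test of gene lists with a preset correlation, lists of cell division, lipid and cholesterol synthesis, the respiratory chain and hepatocyte function were lower with EA. Lists of immediate early genes, glycolysis and hypoxia, p53 targets and YAP/TEAD targets were higher, while 0 of 29 lists passed when the correlation between genes was estimated (4 at an unadjusted p under 0.05, and 22 passed by fry). The matrix metalloproteinase MMP3 (ENSG00000149968) went from 4.29 ± 0.388 to 1654 ± 108 CPM (read counts scaled to normalised library size; mean ± SD, n = 3 per group), and the fibronectin receptor subunit ITGA5 (ENSG00000161638) from 0.988 ± 0.113 to 382 ± 32.1. In the other direction, the hepatic sulfotransferase SULT2A1 (ENSG00000105398) went from 127 ± 5.51 to 2.86 ± 0.319 CPM and the mitotic cyclin CCNB1 (ENSG00000134057) from 159 ± 0.830 to 11.2 ± 1.81. Of 15648 genes tested, 12680 (81.0%) passed an adjusted p of 0.05 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 6344 of them higher and 6336 lower with EA. Levels were scaled within each library, so higher and lower are relative to the other genes. The near-even split says nothing of the amount of RNA per cell. A fold change of 2 or more was estimated for 3661 of the higher and 3367 of the lower genes. In 98.4% of the called genes the 3 EA values all lay on one side of the 3 DMSO values, against 83.0% of all tested genes and the 10% that chance gives.

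**Figure D1:**
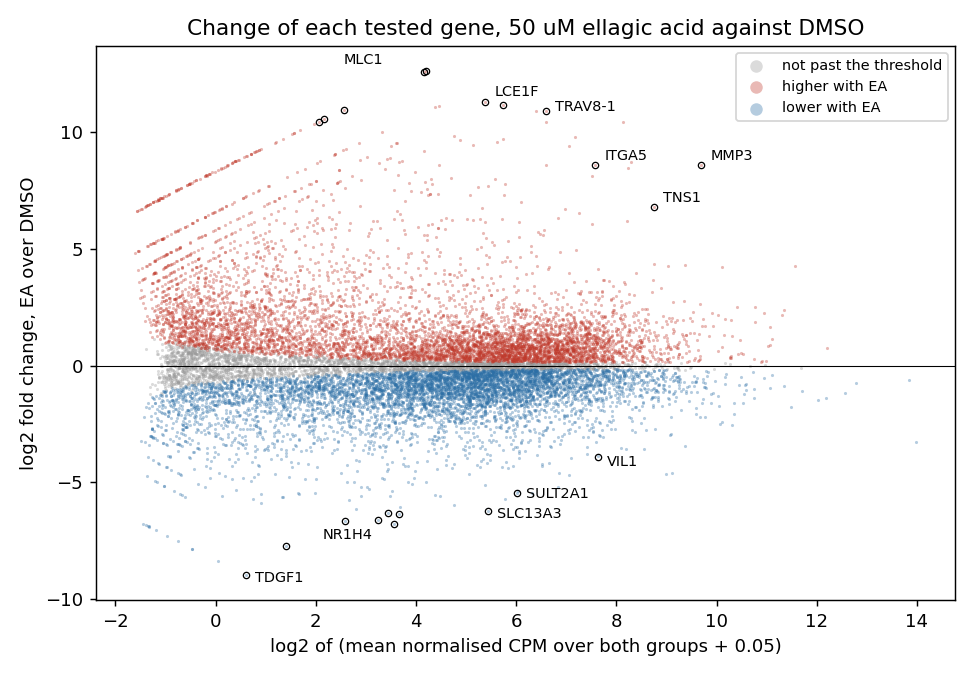
Each point is a tested gene, with the log2 of its mean normalised CPM over both groups plus 0.05 on the x axis and the log2 fold change of EA over DMSO on the y axis. Red points (6344 genes) were higher and blue points (6336 genes) lower with EA at an adjusted p under 0.05. Open circles mark named genes, and the slanted lines of points at the left are genes with few or no reads in one group, whose fitted change depends on the prior count.

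The libraries parted by treatment. The first principal component of log2 CPM held 94.3% of the variance and separated EA from DMSO, with DMSO libraries between -104.73 and -101.47 and EA libraries between 99.23 and 106.68. Pearson correlations of log2 CPM across genes were 0.988 to 0.995 within groups and 0.835 to 0.850 between groups. EA replicate 3 lay apart from EA replicates 1 and 2 on the second component (33.78 against -18.54 and -14.19), which held 2.49% of the variance. Without it 13613 of 16444 genes were called. The apolipoprotein gene APOB took the most reads in every DMSO library, at 2.85% to 3.06% of the total, and the fibronectin gene FN1 in every EA library (1.17% in EA replicate 1). The 20 genes with the most reads held 10.9% ± 0.101 of the reads in DMSO and 7.22% ± 0.176 in EA (SD, n = 3).

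Among the largest increases were genes with few or no reads in the DMSO libraries. MLC1 (ENSG00000100427), which encodes a membrane protein known from astrocytes, had 0 reads over the DMSO libraries and 1997 over the EA libraries, which made it at least 920.8-fold higher against a floor of 3 reads over the group. By the same measure SLC24A2, a cation exchanger gene, was at least 899.6-fold higher, the long non-coding RNA LINC02404 at least 285.4-fold, the cytokine gene CSF2 at least 220.4-fold and the mucin gene MUC16, which encodes the CA125 antigen, at least 202-fold. The cornified envelope gene LCE1F went from 2 to 4501 reads, a ratio of 3110 (95% counting interval 861 to 25700), and LINC02582 from 3 to 5752 reads, a ratio of 2650 (907 to 12900). TRAV8-1, a T cell receptor variable segment, was read at 193 ± 61.5 CPM with EA against 0.0931 ± 0.126 with DMSO. Because the strand used in counting is not stated, reads of an overlapping or antisense transcript cannot be told apart from its own. The genes with the smallest p among those that rose were MMP3 (log2 fold change 8.59, SE 0.11), ITGA5 (8.59, SE 0.12), the focal adhesion gene TNS1 (6.79, SE 0.10) and EMP1 (6.07, SE 0.09), with adjusted p from 4.48e-17 to 1.62e-16 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment.

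TDGF1 (ENSG00000241186), the gene of the embryonic growth factor cripto, had 218 reads over the DMSO libraries and 0 with EA, so it was at least 52.53-fold lower. The acyl-CoA synthetase gene ACSM2B went from 385 reads to 1, a ratio of 0.00359 (95% counting interval 9.07e-05 to 0.0201). NR1H4, the bile acid receptor gene, fell by 6.80 on the log2 scale (SE 0.25), from 23.4 ± 0.963 to 0.197 ± 0.197 CPM. The sodium channel gene SCN1A had a log2 fold change of -6.66 and the alcohol dehydrogenase gene ADH4 one of -6.60. Those of the hepatic glucose transporter gene SLC2A2, of PRODH2 and of the dicarboxylate transporter gene SLC13A3 were -6.37, -6.33 and -6.23. SEs of these genes ran from 0.17 to 0.32. The smallest p among genes that fell were those of SULT2A1 (-5.46, SE 0.10), the transcriptional inhibitor ID1 (-4.61, SE 0.09), the microvillar actin-binding gene VIL1 (-3.89, SE 0.08) and IGDCC3 (-4.69, SE 0.09), with adjusted p from 1.97e-15 to 3.68e-15 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment.

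**Figure D2:**
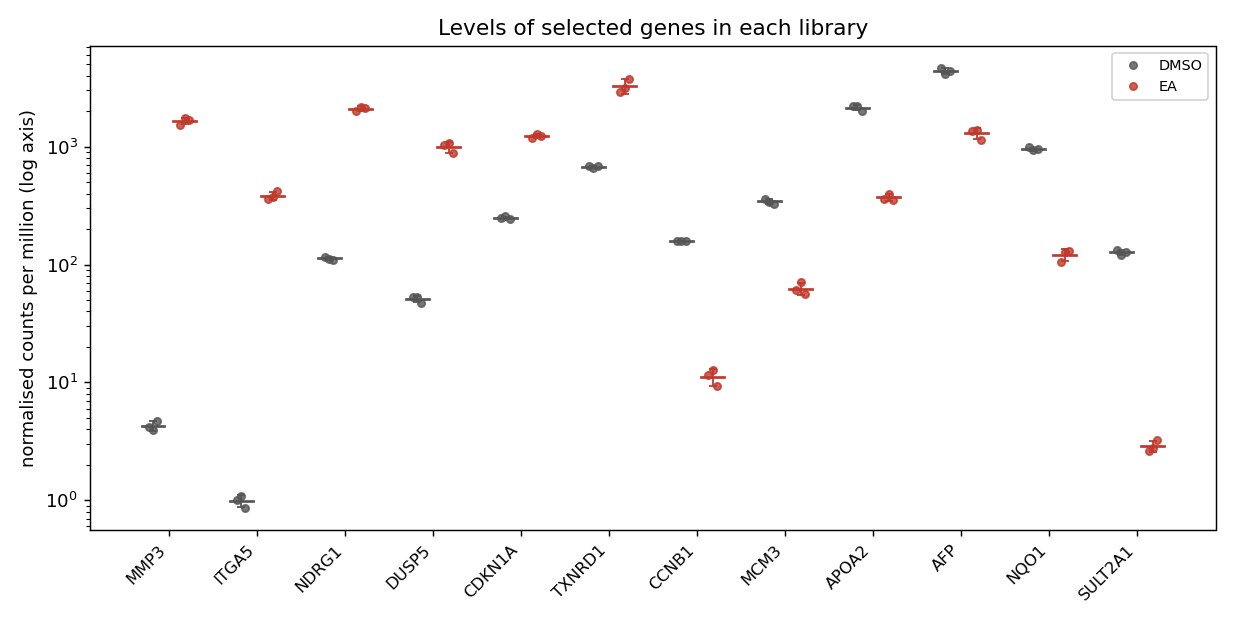
Normalised CPM on a log axis for 12 named genes, with a point per library, a bar at the mean and whiskers of 1 SD (3 DMSO libraries in grey, 3 EA libraries in red). For each gene shown the EA libraries lie wholly above or wholly below the DMSO libraries, from MMP3 (4.29 to 1654 CPM) to SULT2A1 (127 to 2.86 CPM).

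Of 30 gene lists fixed before the data were examined, 29 had at least 3 tested members, and 14 passed an adjusted p of 0.05 in limma's camera test with a preset inter-gene correlation of 0.01, 6 upward and 8 downward. With an estimated correlation camera called 0 of the 29, with 4 at an unadjusted p under 0.05. By contrast fry, which asks only whether a list's genes move on balance one way, called 22. For ERK/MAPK, p53, apoptosis and fetal liver genes the estimate was -0.007, -0.016, -0.017 and -0.096, under the preset 0.01. A higher correlation among their own genes therefore did not raise the p of these lists in that setting. Adjusted over the list alone, the numbers of members higher and lower were the same as over all genes in each of the 29 lists. Since 12680 genes were called and 12824 had an unadjusted p under 0.05 in edgeR's test, these adjustments had little room to differ. Adjusted p-values of lists below are from camera with Benjamini-Hochberg adjustment over the 29 lists.

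Cell division genes fell together. All 22 tested genes of G2/M and mitosis were lower with EA, with a median log2 fold change of -2.18 (adjusted p = 5.33e-07, and 0.485 with an estimated correlation). CCNB1 fell by 3.82 on the log2 scale (SE 0.10), and log2 fold changes were -3.44 for the spindle checkpoint kinase BUB1B and -2.29 and -1.65 for the mitotic kinases AURKA and PLK1. Of 23 genes of DNA replication and S phase, 21 fell and 2 were not called (median -1.68, adjusted p = 2.09e-06, and 0.485 with an estimated correlation). Thymidylate synthase TYMS went from 87.4 ± 6.62 to 14.3 ± 1.02 CPM, and the replicative helicase genes MCM3, MCM5 and MCM6 had log2 fold changes of -2.45, -2.24 and -2.19. Replication-dependent histone genes, whose transcripts mostly lack a poly(A) tail, went the other way, with 9 of 11 higher, 1 lower and 1 not called (median 2.12, adjusted p = 0.0284, and 0.485 with an estimated correlation). HIST1H1C rose from 7.06 ± 0.598 to 56.7 ± 7.78 CPM, and HIST1H4H, HIST1H2BD and HIST2H2BE rose by log2 fold changes of 4.45, 2.40 and 2.74. The histone call was lost after correction for GC content and length (adjusted p = 0.0707). Reads of near-identical histone copies may be split between genes. If RNA was selected by its poly(A) tail, which is not stated here, the histone reads would come mainly from transcripts with a tail.

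Genes of the p53 response and of apoptosis rose. Among 21 p53 targets, 17 were higher, 3 lower and 1 not called (median 0.79, adjusted p = 0.00464, and 0.25 with an estimated correlation). The cell cycle inhibitor CDKN1A rose from 249 ± 6.21 to 1228 ± 54.2 CPM, the stress cytokine GDF15 from 826 ± 48.6 to 4372 ± 380, the p53 ligase MDM2 from 152 ± 1.07 to 454 ± 43.4 and the pro-apoptotic BBC3 from 19.1 ± 1.17 to 71.7 ± 9.03. Another pro-apoptotic target, BAX, fell by 1.77 on the log2 scale (SE 0.10). Of 21 apoptosis regulators, 17 were higher, 2 lower and 2 not called (median 0.66, adjusted p = 0.00363, and 0.25 with an estimated correlation). These included both promoters and inhibitors of cell death, with log2 fold changes of 3.33 for PMAIP1 and 1.76 for BCL2L11, which promote it, and of 1.18 for CFLAR, which blocks caspase activation at death receptors. BBC3 belonged to both lists.

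Immediate early genes and feedback regulators of the ERK pathway were higher with EA in 15 of 17 cases and lower in 2 (median 1.58, adjusted p = 8.53e-05, and 0.25 with an estimated correlation). FOS rose from 3.32 ± 0.224 to 84.3 ± 8.25 CPM, the ERK phosphatase gene DUSP5 from 50.9 ± 3.16 to 991 ± 103, EGR1 from 83.9 ± 5.89 to 757 ± 42.7 and JUN from 119 ± 7.38 to 646 ± 1.84. The 2 that fell were the ETS factors ETV4 (-0.37, SE 0.06) and ETV5 (-0.91, SE 0.08). Among 10 YAP/TEAD targets, 8 rose, 1 fell and 1 was not called (median 1.895, adjusted p = 0.00673, and 0.485 with an estimated correlation), with log2 fold changes of 2.42 for ANKRD1, 2.32 for NUAK2, 1.78 for AMOTL2 and 1.72 for LATS2. Glycolysis and hypoxia genes rose in 17 of 20 cases, with 1 lower and 2 not called (median 1.86, adjusted p = 2.28e-05, and 0.457 with an estimated correlation). The prolyl hydroxylase EGLN3, itself a target of hypoxia-inducible factors, rose from 2.86 ± 0.123 to 227 ± 35.3 CPM. PFKFB3, which makes an activator of glycolysis, rose from 9.01 ± 0.193 to 282 ± 25.1. NDRG1 rose from 113 ± 3.24 to 2106 ± 100 and the peptide hormone gene ADM from 9.54 ± 0.735 to 151 ± 13.1.

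Of 24 genes of hepatocyte secretion and differentiation, 22 fell, 1 rose and 1 was not called (median -2.14, adjusted p = 3.47e-06, and 0.362 with an estimated correlation). The retinol carrier RBP4 went from 364 ± 21.3 to 54.6 ± 0.648 CPM, the apolipoprotein APOA2 from 2147 ± 116 to 371 ± 23.9, the asialoglycoprotein receptor subunit ASGR1 from 318 ± 17.4 to 51.9 ± 6.51 and the fibrinogen chain FGB from 174 ± 8.59 to 8.97 ± 1.87. By contrast APOA1, the main protein of high-density lipoprotein, rose by a log2 fold change of 0.35 (SE 0.13). Fetal liver and liver tumour markers fell in 9 of 11 cases and rose in 2 (median -1.01, adjusted p = 0.0495, and 0.446 with an estimated correlation). Alpha-fetoprotein (AFP) went from 4405 ± 250 to 1295 ± 135 CPM, and EPCAM and PEG10 had log2 fold changes of -1.64 and -1.62, whereas the biliary keratin KRT19 rose by 1.68. The call of this list was lost without the 20 genes with the most reads (adjusted p = 0.11), after correction for GC content and length (0.0685), with a stricter filter (0.0662) and without EA replicate 1 or EA replicate 2 (0.0501 and 0.0512).

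In cholesterol synthesis and uptake 16 of 19 genes fell, 2 rose and 1 was not called (median -1.38, adjusted p = 9.13e-05, and 0.485 with an estimated correlation). INSIG1, CYP51A1 and EBP, the other members, had almost no reads in any library for a reason not given in the sources used here, and were not tested. Among those that fell, ACAT2, FDFT1 and DHCR7 had log2 fold changes of -3.10, -2.26 and -1.73. All 10 tested genes of fatty acid synthesis fell (median -1.55, adjusted p = 0.000388, and 0.485 with an estimated correlation), among them the desaturase genes FADS2 (-3.21), SCD (-2.08) and FADS1 (-1.57) and fatty acid synthase FASN (-1.53). Of 23 nuclear genes of the respiratory chain, 22 fell and 1 was not called (median -1.08, adjusted p = 5.33e-07, and 0.485 with an estimated correlation), over a narrow range of log2 fold changes from -1.75 to -0.13. UQCRC2 had a log2 fold change of -1.75 (SE 0.07), NDUFV1 of -1.47 (SE 0.08), and the ATP synthase subunits ATP5F1B and ATP5F1A of -1.44 and -1.37. Over all tested genes in 4 classes of transcript length, from shortest to longest, the median log2 fold changes were -0.11, -0.20, -0.02 and 0.28. The respiratory chain median after correction for GC content and length was -0.96. The 13 genes of a separate list of mitochondrially encoded proteins were at 0 reads in all 6 libraries, as were all 37 genes named MT- in the table, and could not be tested. Chaperones of the endoplasmic reticulum and other genes of its stress response fell in 9 of 13 cases, with 3 higher and 1 not called (median -1.07, adjusted p = 0.0454, and 0.599 with an estimated correlation). XBP1 went from 409 ± 10.0 to 80.2 ± 8.19 CPM and PDIA4, CALR and HSP90B1 had log2 fold changes of -1.76, -1.60 and -1.31. The call of the list was lost after correction for GC content and length (adjusted p = 0.0685), with a stricter filter (0.0623) and without EA replicate 1 (0.0501).

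Some members went against their list or were not called, and these were picked out after their values were seen. In the cholesterol list SC5D stood at a log2 fold change of 0.03 (SE 0.08, not called). SLC2A1, the widely expressed glucose transporter, fell by 0.49 on the log2 scale within the glycolysis and hypoxia list, and ALDOC (0.08) and P4HA1 (-0.08) were not called. The pro-apoptotic genes BAX and BID (-1.10) were the lower members of the apoptosis list, and TNFRSF10B (-0.36) and SPATA18 (-0.34) joined BAX among the lower p53 targets. Not called were SESN1 (-0.12) in the p53 list, BIK (0.12) among apoptosis regulators, and CCNE2 (-0.15) and CDT1 (-0.70) in S phase. The same held for F3 (0.02) among YAP/TEAD targets, NDUFS1 (-0.13) in the respiratory chain, PCK1 (0.17) in the hepatocyte list, HIST1H4C (-0.37) among histones and HERPUD1 (0.11) in the endoplasmic reticulum list. There DNAJB9 (1.33), EDEM1 (0.78) and DNAJC3 (0.56) rose, and elsewhere AJUBA (-0.19) and HIST2H2AC (-3.14) fell while the growth factor gene IGF2 rose (1.31).

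**Figure D3:**
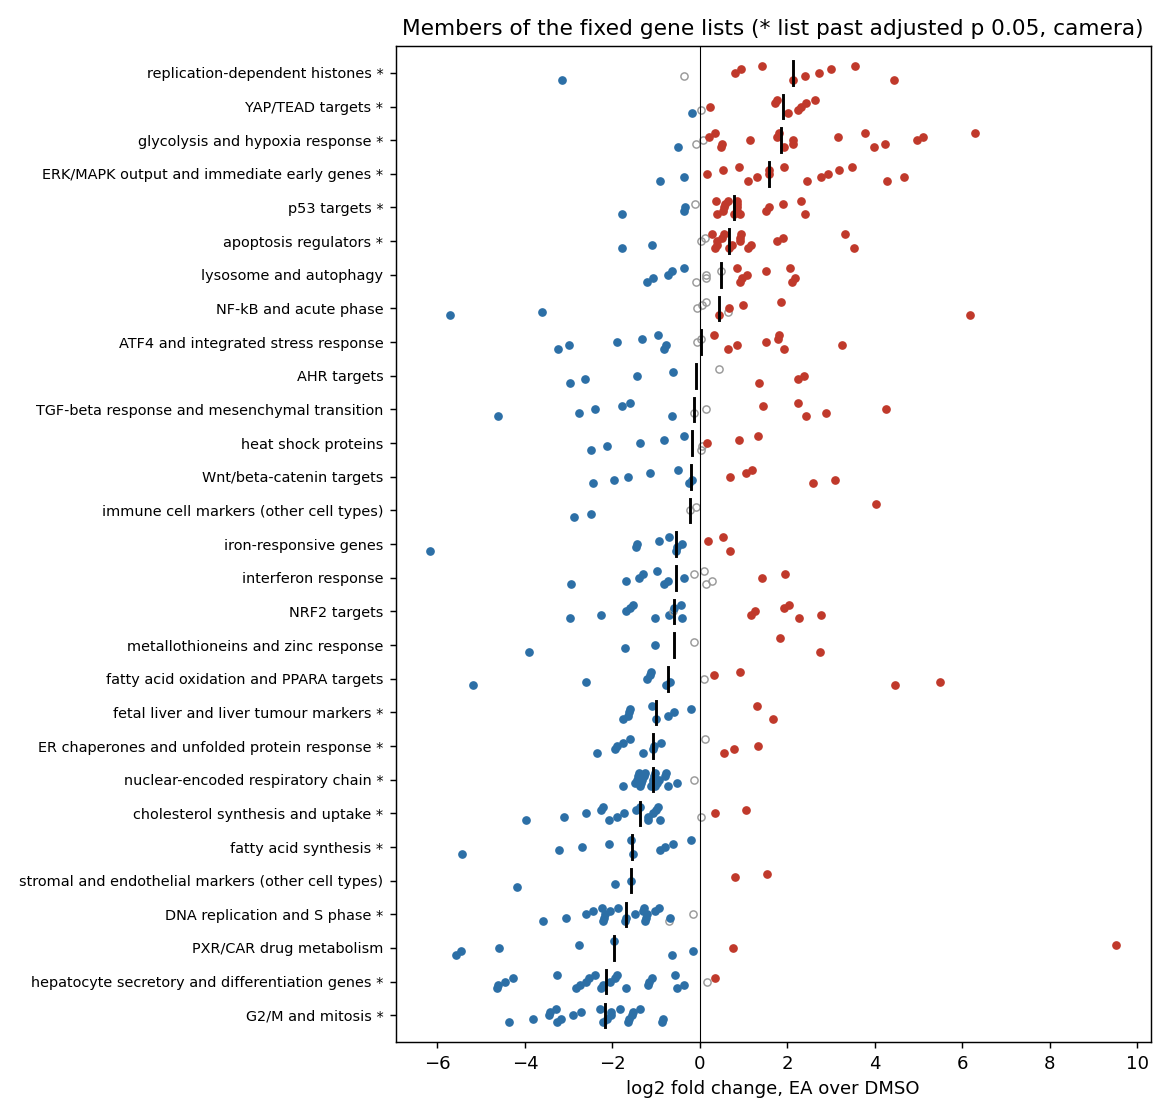
Each point is a tested member of a gene list, placed by its log2 fold change of EA over DMSO. Filled points passed an adjusted p of 0.05 (red higher, blue lower), open points did not. Black bars are list medians, and stars mark the 14 lists past an adjusted p of 0.05 in camera with the preset correlation, whose medians run from -2.18 for G2/M and mitosis to 2.12 for replication-dependent histones.

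Several lists of responses to stress and foreign compounds split between higher and lower members and did not pass camera. Of 17 NRF2 targets, 6 rose, 10 fell and 1 was not called (adjusted p = 0.416). The glutathione synthesis gene GCLC rose from 167 ± 4.52 to 1137 ± 43.7 CPM and thioredoxin reductase TXNRD1 from 676 ± 14.4 to 3264 ± 457, while the quinone reductase NQO1 fell from 953 ± 28.6 to 121 ± 13.8. Targets of the aryl hydrocarbon receptor AHR went both ways, with 3 of 8 higher, 4 lower and 1 not called (adjusted p = 0.933). TIPARP and the receptor's repressor AHRR had log2 fold changes of 2.39 and 2.26, and NQO1, a member of both lists, and SLC7A5 of -2.97 and -0.62. In the ATF4 list 8 of 17 rose, 7 fell and 2 were not called (adjusted p = 0.933), the serine and one-carbon enzymes PHGDH (-3.25) and SHMT2 (-1.89) and mitochondrial PCK2 falling and the mTOR inhibitor DDIT4 (1.82) rising. Heat shock genes were higher in 3 of 10 cases, lower in 5 and not called in 2 (adjusted p = 0.519), with the mitochondrial chaperonin genes HSPE1 (-2.49) and HSPD1 (-1.37) lower and HSPH1 (1.33) and BAG3 (0.90) higher. For metallothioneins and zinc-responsive genes the counts were 2 higher, 3 lower and 1 not called of 6 (adjusted p = 0.933), with MT2A at 71.1 ± 5.19 to 478 ± 58.9 CPM, MT1X higher (1.83) and MT1E lower (-1.03). Reads of these near-identical paralogs may be shared. Iron-responsive genes were lower in 8 of 11 cases and higher in 3 (adjusted p = 0.128). The iron hormone gene HAMP fell from 13.7 ± 1.07 to 0.189 ± 0.0741 CPM, the ferritin light chain FTL from 6127 ± 205 to 2213 ± 149, and ACO1 and SLC11A2 had log2 fold changes of -0.93 and -0.70.

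Among 9 tested genes of PXR/CAR drug metabolism 7 fell and 2 rose (median -1.96, adjusted p = 0.217). Here SULT2A1 and GSTA1 (-5.58, SE 0.26) fell, while ALAS1, the first enzyme of haem synthesis, rose by 0.75. In fatty acid oxidation and PPARA targets 4 of 12 rose, 7 fell and 1 was not called (adjusted p = 0.416). The lipoprotein lipase inhibitor ANGPTL4 rose from 1.84 ± 0.370 to 82.0 ± 14.1 CPM and VNN1 from 5.04 ± 0.493 to 112 ± 8.63, while HADHB had a log2 fold change of -1.13. For TGF-beta response and mesenchymal transition 5 of 13 genes rose, 6 fell and 2 were not called (adjusted p = 0.762), with ID1, CDH2 (-2.39) and TGFBI (-2.75) lower and ZEB1 (2.24) higher. NF-kB and acute phase genes were higher in 5 of 11 cases, lower in 2 and not called in 4 (adjusted p = 0.519). The NF-kB subunits RELB (1.85) and NFKB2 (0.67) rose, and the acute phase proteins haptoglobin HP (-5.72) and ORM1 (-3.61) fell, ORM1 having a close paralog that may share its reads. Interferon response genes fell in 8 of 14 cases, rose in 2 and were not called in 4 (adjusted p = 0.289), with log2 fold changes of -1.40 for BST2, -0.82 for OAS1 and 1.43 for IFI6. Wnt/beta-catenin targets split into 5 higher and 7 lower of 12 (adjusted p = 0.762), with AXIN2 higher (3.10) and LGR5 (-1.95), SP5 (-1.63) and NOTUM (-2.44) lower. Lysosome and autophagy genes rose in 8 of 17 cases, fell in 5 and were not called in 4 (adjusted p = 0.3). The autophagy kinase ULK1 (2.10), the protease CTSB (2.18), GABARAPL1 (2.07) and MAP1LC3B (1.09) all rose.

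The lists of markers of other cell types did not pass camera, and fry called the immune list lower (adjusted p = 5.76e-05). Of 5 tested immune markers 1 was higher, 2 lower and 2 not called (adjusted p = 0.598), with lysozyme LYZ, which HepG2 cells themselves expressed at 1810 ± 45.3 CPM with DMSO, at 324 ± 33.0 with EA. The macrophage receptor CSF1R was higher (4.02, SE 0.38) and the monocyte marker CD14 lower (-2.88, SE 0.44), both named after their values were seen. Among 5 stromal and endothelial markers 2 were higher and 3 lower (adjusted p = 0.762), with log2 fold changes of -1.58 for PDGFRB, 0.81 for ACTA2 and 1.53 for VWF. The direction of a list's median, mean, camera and fry tests did not coincide for AHR targets, for metallothioneins, for ATF4 (fry downward, the others upward) and for Wnt targets (mean 0.05 against a median of -0.21). The medians of the AHR, heat shock and TGF-beta lists turned positive after correction for GC content and length (0.11, 0.11 and 0.06), and that of the ATF4 list (0.02) changed sign among the alternatives, while those of the 14 called lists did not.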

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

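The tests with equal depth, without the 20 most-read genes and of lists after GC and length correction were chosen after the results were seen. Counts of called genes stayed within 1.5 times of 12680 under every alternative run, from 11130 with a minimum fold of 1.2 to 14923 of 32015 genes without a filter, which shifted the median log2 fold change by -0.13. DESeq2 called 11859 of the 12680 genes (93.5%) in the same direction. Leaving out 1 library gave 12302 to 13613 calls. For the 131 named genes all 1310 values under 10 alternatives kept direction and call. These genes had been chosen from the same counts for being called and fully separated, so this says little about other genes. Replicate numbers gave no sign of pairing. Correlations of deviations were -0.17, 0.07 and 0.05 between same-numbered libraries, against -0.14 to 0.09 between unlike numbers. So few values, taken around group means of 3 libraries, cannot show that the samples were unpaired. With the replicate block 12537 genes were called and no list changed its call. Of 406 alternative list tests 375 kept direction and side of the threshold. The camera setting with an estimated correlation took the called lists from 14 to 0. Its adjusted p was 0.25 (ERK/MAPK, p53, apoptosis), 0.362 (hepatocyte), 0.446 (fetal liver) and 0.457 (glycolysis). It was 0.485 for S phase, G2/M, histones, cholesterol, fatty acid synthesis, respiratory chain and YAP/TEAD, and 0.599 for endoplasmic reticulum. These were the highest of the 14 alternatives for all 14 lists, whose lowest ran from 1.19e-09 to 0.000353. For ERK/MAPK, p53, apoptosis and fetal liver genes the estimate lay under the preset correlation, so a higher correlation among their own genes did not raise their p. fry called 22, adding iron (0.000156), heat shock (0.00349), PXR/CAR (0.000553), TGF-beta (0.00236), interferon (0.000668), lysosome (9.64e-05) and immune markers (5.76e-05), and reversed metallothioneins to upward (0.00349). The stricter filter ended the endoplasmic reticulum (0.0623) and fetal liver (0.0662) calls, as did GC and length correction (0.0685 for both), which also ended the histone call (0.0707), and removal of the 20 most-read genes ended the fetal liver call (0.11). With libraries left out these 2 lists ranged over 0.0298 to 0.0501 (above 0.05 without EA replicate 1) and 0.0361 to 0.0512 (without EA replicate 1 or 2), and 12 to 14 lists were called. Why these calls ended was not tested. Depth limits what can be said of genes near 0.116 to 0.191 CPM, the level that 3 reads give in 1 library.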

Other observations

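The tests of thinned libraries, of the 20 most-read genes, of lists after GC and length correction, of dilution, of genomic DNA and of library totals were chosen after the result was seen. So were the 14 gene families that follow, formed by symbol and partly around genes that had stood out, so only counts and medians are given. Of 12 matrix metalloproteinase genes 9 rose, 2 fell (MMP11 and MMP15) and 1 was not called (MMP24), but MMP1, MMP9, MMP10, MMP13 and MMP19 passed the filter only through their EA reads and could be tested only if higher. MMP1, the interstitial collagenase, went from 0.386 ± 0.189 to 266 ± 92.4 CPM and MMP10 from 0.119 ± 0.0652 to 107 ± 26.1. Integrin subunits rose in 12 of 18 cases and fell in 4 (median log2 fold change 0.75). The higher ITGAX (0.180 ± 0.115 to 39.7 ± 0.852 CPM) and ITGAM passed the filter only through EA and could be tested only if higher. The lower ITGAL and ITGA9 passed only through DMSO and could be tested only if lower. Tested genes of late cornified envelope and small proline-rich proteins had 0 to 6 reads over the DMSO libraries and passed the filter through their EA reads, so that they could be tested only if higher, SPRR2D going from 0.0812 ± 0.00506 to 24.8 ± 12.9 CPM. On the other side 11 of 11 coagulation genes fell (median -1.97), among them F11 (-3.88) and F7 (-3.15). Of 18 complement genes 15 fell, 1 rose (C1R) and 2 were not called (median -1.64), C5 going from 189 ± 11.6 to 16.7 ± 0.724 CPM. Alcohol and aldehyde dehydrogenase genes fell in 16 of 19 cases and rose in 1, ALDH1A2 (median -2.11). Of these, C6, C7, C8A, C8B, KNG1, ADH4 and ALDH8A1 passed the filter only through their DMSO reads and could be tested only if lower.

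Families of protein synthesis and turnover held mostly lower members, with smaller changes that are relative to the other genes. Of 76 cytosolic ribosomal protein genes 75 fell (median -0.96). Of 74 mitochondrial ribosomal protein genes 64 fell and 2 rose (median -1.07). Of 36 proteasome subunit genes 31 fell and 3 rose (median -0.83), and all 8 subunit genes of the chaperonin TRiC fell (median -0.81). Aminoacyl-tRNA synthetase genes fell in 12 of 17 cases and rose in 3 (median -0.65), and genes of RNA polymerase I and ribosomal RNA processing in 23 of 33 with 5 higher (median -0.39). With GC and length correction, other scalings or no filter the medians were no higher than -0.82 for cytosolic ribosomal proteins and -0.86 for mitochondrial ones. Zinc finger genes named ZNF rose in 250 of 403 cases and fell in 75 (median 0.57), while SNHG host genes, GAS5, MALAT1 and NEAT1 gave 7 higher and 10 lower of 21. Some zinc finger genes, such as ZNF365, ZNF470, ZNF28 and ZNF418, passed the filter only through EA and could be tested only if higher. Others, such as ZNF93 and ZNF385B, passed only through DMSO and could be tested only if lower. By class, 46.7% of called protein-coding genes were higher with EA, against 67.0% of long non-coding genes and 63.3% of pseudogenes. In each class, genes with few reads in one group could pass the filter only through the other. How far this sets these shares was not tested.

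The first pattern weighed is the number of genes called. The 10 splits of the 6 libraries into groups of 3 are too few for a share under 0.05. The real split gave 12680 calls by edgeR's quasi-likelihood test and 1 split, the real one, reached that number. The highest of the other 9 was 0, with 1 to 31 genes at an unadjusted p under 0.05. Each of those 9 splits puts EA and DMSO libraries in the same group, so the difference between them adds to the spread within groups. Few calls there would follow whatever the source of that difference, so the splits decide nothing about chance. EA libraries were shallower, but 12102 genes were called after all libraries were thinned to the smallest total, which argues against depth as the source. Removing the 20 genes with the most reads left 12635 calls, which argues against a few abundant genes setting the scale. The labels do not say whether the groups were grown and sequenced together, so a difference between batches cannot be told apart from an effect of EA. A broad response to EA remains a hypothesis.

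The second pattern is the fall of hepatocyte genes. If dilution of the HepG2 RNA by cells lacking liver genes were the whole cause, 12 abundant liver transcripts would have fallen alike. Yet the extremes, APOC3 (-4.45, SE 0.19) and APOA1 (0.35, SE 0.13), lay 4.16 apart on the log2 scale after 2 SEs were taken off at each end. That argues against dilution alone, but the span cannot exclude dilution together with changes of single genes. The list's median was -2.05 after correction for GC content and length and its call stayed (adjusted p = 6.4e-06, in a range of 5.68e-07 to 0.362 over its alternatives), which argues against that trend as the whole cause. EA libraries made from another liver line, or a divergent stock of HepG2, cannot be told apart from an effect of EA, since autosomal medians differed from that of all autosomes by at most 0.28 (chromosome 22, SE 0.12), a small shift whose error leaves room for other copy numbers. A loss of hepatocyte traits under EA is a hypothesis that may account for the rest.

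The third pattern is the reading of genes that were silent in DMSO. Of 25335 genes with 0 reads in all DMSO libraries, 99 had at least 10 in each EA library (47 protein-coding, 35 long non-coding, 14 pseudogenes and 3 others, among them CSF2, MUC16 and MYOD1), against 15 of 22593 in the reverse direction, APOA5 and SULT1E1 included. Each EA library had reads in more genes (25223 to 25583) than each DMSO library (23119 to 23523) without being deeper (largest EA total 0.835 of the smallest DMSO total), so traces of genomic DNA stay open, but as the source of the 99 genes it would have put reads in most silent genes, whose median count per EA library was 0, as over the 4046 others at least as long as the median of the 99 (66.8% with no EA read). Transcription running over from neighbouring genes cannot be told apart. The nearest expressed neighbours of the 99 genes had a median log2 fold change 0.09 above those of 23953 genes silent in DMSO (one-sided permutation p = 0.29, 10000 draws). Not all of the latter stayed silent, since 80.5% of genes with 0 DMSO reads had 0 EA reads. The difference of 0.09 neither shows nor excludes such transcription. Induction by EA is a candidate explanation that was not tested further.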
